A study of Mus musculus with 2 samples.

How the data were processed

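Single-cell RNA sequencing of mouse pancreatic ductal adenocarcinoma was analysed, with 1 library of the whole tumour and 1 library of cells sorted for high surface CD9. Per the labels' protocols, tumours were dissociated with collagenase and TrypLE, live cells were sorted on GFP or CD9, and droplet libraries of transcript 3′ ends were made with the Chromium Next GEM chemistry. The tumours came from a mouse line in which Flp recombinase, driven by the Pdx1 promoter in the pancreas, deletes Trp53, and which carries a membrane Tomato to membrane GFP reporter. The group of each library was taken from the sorted population named in its labels. Each group had 1 library, so cells were not treated as replicates and no test between the groups was made.

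The deposited values were raw UMI counts per gene and barcode, per the file headers, with no normalization by the authors. Reads were aligned to GRCm39 with Cell Ranger 7.0.0, per the submitters' processing notes, whereas the version recorded in the matrices was 6.1.2, per the file headers. Whether intronic reads were counted was not given in the sources used here. The matrices held 55361 features, of which GFP and TdTomato were added reporter sequences and 1705 shared their symbol with another feature, and these were kept apart by identifier. Counts of members of multigene families, such as the Reg, Klra, Gzm, Mcpt and trypsinogen genes, can be split between near-identical copies and are uncertain.

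The choices below were made before the data were examined unless stated otherwise. Barcodes with at least 500 detected genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept, which removed 532 of 3082 barcodes of the whole tumour and 408 of 5500 of the CD9hi library. Doublets were removed as the highest Scrublet scores in each library at an expected rate of 0.8% per 1000 barcodes, which took out 63 and 224 cells. Scrublet's automatic threshold marked 0.549% and 0.0196% of cells, so in the CD9hi library the automatic call did not work. The analysis then held 2487 whole-tumour cells with a median of 17626 UMIs and 4868 CD9hi cells with a median of 21631.5 UMIs.

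Cells of both libraries were clustered together without integration in scanpy 1.11.5 on log-transformed counts per 10000, with 2000 variable genes, 30 principal components from scikit-learn 1.9.0, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 0.8. The 19 clusters were named from 17 fixed lists of cell type markers. A marker passed in a cluster at a mean CPM of at least 50, in at least 25% of cells and at 10% or more of the highest cluster's level. A name required that no fewer markers of the list passed than failed, with either 3 of its markers among the 10 leading genes of the cluster or at least 3 markers passing and no other type leading. This scoring rule was set after the clusters were seen, as was a list of tuft cell genes that kept cluster 17 unnamed. Cluster 17 held 0.643% of whole-tumour cells and 0 of 4868 CD9hi cells, which allows a share of up to 0.0616%. The tumour population was all cells outside clusters named as immune, stromal, acinar, islet or other non-tumour types. It included the unnamed clusters 5, 7, 10, 11, 12 and 17, which held 11.5% of whole-tumour cells and 32.0% of CD9hi cells. Of these, cluster 11 was led mostly by acinar genes, with Ptf1a at 176 CPM and Epcam at 1297 CPM, and cluster 7 by matrix genes also found in fibroblasts, so the population can hold cells of other types. Clusters 0, 2, 8 and 13 were named ductal epithelial by marker levels although they had more Vim than Epcam, and the leading genes of cluster 8 were mostly matrix genes such as Tnc and Bgn.

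Counts were summed over the tumour population of each library and divided by their total to give CPM, the counts in each 1 M UMIs. Ratios are log2 of CD9hi over whole tumour, with 0.5 counts added to each sum. Genes with a mean CPM of at least 5 counted as measured, which held for 9757 genes with a median ratio of 0.02. Intervals are 95% intervals, exact Poisson or conditional binomial for counts and exact Clopper-Pearson for shares, and they cover counting error only. The interval of a difference between shares combined the widths of both intervals as independent. To judge shifts under alternatives, list medians had intervals from 200 Poisson draws of the counts, and median entropies had order-statistic intervals over cells, which are not printed because they describe cells and not libraries. For each of 26 fixed gene lists, the members at least 1.5-fold higher or lower were counted as a rule of size, and the median was placed among the medians of 10000 random lists of the same size matched on mean expression. The lists were epithelial identity, mesenchymal state, EMT transcription factors, Notch ligands and receptors, Notch regulators and targets, pancreatic tumour-initiating markers, tetraspanins, classical subtype, basal subtype, mucins, proliferation, glycolysis, hypoxia, respiratory chain, glutamine and amino acid metabolism, TGF-beta, YAP, laminins and integrins, fibrillar collagens, immediate early and heat shock genes, unfolded protein response, interferon, antigen presentation, NF-kB, Wnt, and EGFR and MAPK output.

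Genes were named by a fixed rule. It took 15 genes chosen from the study's subject, the 15 highest and 15 lowest ratios among genes with a mean CPM of at least 50 and a count of at least 30 in the higher library, and up to 4 members of each list with the largest shift. It also took the 10 genes of each library with the highest ratio of hybrid cells to both single classes. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and predicted genes were left out, and not every gene that met the rule is named. Genes named for single clusters, and list members named beyond 4 per list, fell outside this rule and were chosen after their values were seen.

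For classes of epithelial and mesenchymal expression, cells of the tumour population were thinned to 2000 UMIs, which left out 25 whole-tumour and 10 CD9hi cells. A cell was high for a list if its UMIs of that list exceeded the whole-tumour median, which was 31 epithelial and 10 mesenchymal UMIs, and hybrid if high for both. Gene levels in the classes used the full counts. Transcriptome entropy was the Shannon entropy in bits of a thinned cell, and proliferating cells had at least 3 UMIs of the proliferation list. The StemID and Slingshot methods named for the study were not run, and only the entropy part of StemID was computed.

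Alternatives covered the cell filter, doublet removal, the population, the weight of cells, TMM factors from edgeR 4.0.16, median-of-ratios factors from DESeq2 1.42.0, thinning, clustering, expression minimums, the fold rule and the class boundaries. Both scalings were used only as factors, with no test. Alternatives that left out clusters were added after the data were seen. The gene ratio and list steps were run on simulated Poisson counts from the mean profile of both libraries, with the real library sizes. For CD9hi over whole tumour, 94 of 94 measured genes changed 2-fold and 96 of 96 changed 4-fold were recovered among 9712 genes. Of 9522 unchanged genes 0 passed the 1.5-fold rule, and intervals covered 95.8% of a subset of them. The simulation had no variation between cells or libraries, so it checks the calculation and not the error of real libraries. No list was changed as a set, and the highest absolute median of the 26 lists was 0.084. Chromosomes and gene order came from a mouse gene table of another assembly, GRCm38.p6, so no coordinates are given.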

Results

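Mouse pancreatic tumour cells were profiled by droplet single-cell RNA sequencing in 2 libraries, 1 of the whole tumour and 1 of cells sorted for high CD9, a tetraspanin of the cell surface. The series concerns a hybrid epithelial and mesenchymal state, the Notch ligand Jag1 and tumour-initiating cells with high CD9. The whole-tumour library held 3082 barcodes with 48287984 UMIs and the CD9hi library 5500 barcodes with 120451299 UMIs. There were no replicates, so no difference between the libraries has a replicate check, and all intervals cover counting error only. Malat1, a nuclear RNA often raised in damaged cells, was at 21802 CPM in the whole-tumour and 21884 CPM in the CD9hi tumour population, and ribosomal protein genes took 16.9% and 17.5% of UMIs. The pooled Malat1 level hides cluster 5, with 12.02% of CD9hi and 0.121% of whole-tumour cells, where Malat1 was at 157 CPM and the median CD9hi cell had 2369 detected genes. Over all barcodes Xist was detected in both libraries, at 916 and 396 CPM, while the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had at most 2 UMIs each.

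The comparison of Cd9 levels asked whether the sort was reflected in the RNA. In the tumour population Cd9 was higher in the CD9hi library, at 2363 CPM against 1465 CPM, a log2 ratio of 0.69 (0.68 to 0.70). After thinning, 95.6% of CD9hi cells (94.98 to 96.16) and 76.8% of whole-tumour cells (74.9 to 78.5) had a Cd9 UMI, against 19.7% (15.5 to 24.5) of acinar-like cells, which served as the background. Without thinning the shares were 99.8%, 97.0% and 66.5% at median depths of 21677, 17910.5 and 16193 UMIs. In the 3 clusters with at least 100 cells of each library, the Cd9 log2 ratio was -0.76 in cluster 0, 0.20 in cluster 6 and 0.03 (-0.014 to 0.073) in cluster 8, and over these clusters together it was -0.33. In the clusters named ductal epithelial it was 0.51, and it was above 0 in 8 of the 11 clusters with cells of both libraries. In clusters with fewer cells of a library, Cd9 was at 2575 CPM in CD9hi and 2462 CPM in whole-tumour cells of cluster 1, at 1791 CPM and 1193 CPM in cluster 3 and at 781 CPM and 687 CPM in cluster 4, but at 2736 CPM in CD9hi cells and 7005 CPM in the 19 whole-tumour cells of cluster 2.

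Among the named classes outside the tumour population, acinar-like cells, which express digestive enzymes of the exocrine pancreas, differed most. They made up 13.1% (11.8 to 14.5) of 2487 whole-tumour cells and 0.0616% (0.0127 to 0.180) of 4868 CD9hi cells. The tumour population made up 85.6% (84.2 to 87.0) and 99.1% (98.8 to 99.4). Its make-up also differed strongly between the libraries. Of whole-tumour and CD9hi cells, cluster 3 held 23.2% and 1.46% and cluster 4 held 22.2% and 0.781%. In the other direction, cluster 1 held 1.89% and 15.9% and cluster 2 held 0.764% and 14.5%. Islet endocrine-like cells took 1.09% and 0.185%, macrophage- or monocyte-like cells 0.121% and 0.493%, and fibroblast-like cells 0.0804% and 0.144%. The sort on GFP or CD9 can set all of these shares. The CD9hi tumour population share was 89.6% where double the expected number of doublets was removed, 90.4% with no doublets removed and 89.9% with no cell filter. Cluster 7, with 9.78% of CD9hi cells, was named fibroblast under some settings, which takes such cells out of the tumour population and can lower its share.

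Within the tumour population, epithelial genes were lower and mesenchymal genes higher in the CD9hi library. Of 26 measured members of the epithelial identity list, 23 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -1.79. Among the lowest were the tight junction gene Tjp3 at -3.62, Rab25 at -3.17 and the transcription factor Elf3 at -2.92, and the adhesion genes Epcam and Cdh1 were at -1.02 (-1.04 to -1.01) and -0.75 (-0.79 to -0.71). Of 23 mesenchymal state genes, 17 were higher and 0 lower, with a median of 1.202, including the cadherin Cdh11 at 5.91 (8 UMIs in the whole tumour), Tgfbi at 5.17, Mmp2 at 5.14 and Tagln at 3.04, and the intermediate filament gene Vim was at 1.86 (1.85 to 1.88). Of 8 measured EMT transcription factors, 6 were higher and 0 lower, with a median of 1.42, led by Prrx1 at 8.14 (7.13 to 9.70, 6 UMIs in the whole tumour), Twist1 at 1.92, Hmga2 at 1.57 and Zeb2 at 1.43, with Zeb1 at 1.11. Of 13 measured fibrillar collagen and matrix genes, 11 were higher, with a median of 1.71, among them Col1a2 at 5.64, Col3a1 at 4.32, Col5a2 at 3.45 and Col5a1 at 3.13. The epithelial median lay at percentile 0 of the random lists and the other 3 medians at percentile 100.

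Cells of other types and single clusters moved with these lists. Collagens are also fibroblast genes, and Col1a1 was at 28.6 CPM in the CD9hi tumour population, 117 CPM in cluster 7 and 9387 CPM in the 9 fibroblast-like cells of cluster 18. Without cluster 7, 21 epithelial genes were lower, and 12 mesenchymal genes, 6 EMT transcription factors and 8 matrix genes were higher. In the clusters named ductal epithelial alone, 7 mesenchymal genes were higher and 2 lower, and the mesenchymal median was 0.36. Without cluster 11, 2 mesenchymal genes were lower. That name covers clusters with more Vim than Epcam, at 4588 CPM and 904 CPM in cluster 0, 6398 CPM and 674 CPM in cluster 2, 5734 CPM and 918 CPM in cluster 8 and 5417 CPM and 875 CPM in cluster 13. Over the 3 clusters shared by the libraries, 9 epithelial genes and 1 mesenchymal gene were lower and 7 mesenchymal genes, 1 EMT transcription factor and 4 matrix genes were higher, with an epithelial median of -0.50 and a mesenchymal median of 0.19. Counts were summed over the 3 clusters here and below, so their mix still differed. Cluster 0 had 956 CD9hi and 230 whole-tumour cells, and cluster 6 had 309 and 260. Within clusters 0, 6 and 8 the epithelial median was 0.30, -0.31 and -0.65.

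Single genes were ranked among those with a mean CPM of at least 50, and the largest ratios included mesenchymal and acinar genes. Some genes below this mean, such as Prrx1 and Cdh11, had ratios above those of all genes ranked here. The 15 highest genes were Klra4 at 4.78 (4.56 to 5.00), Ank at 3.04, the calcium-binding protein gene S100a4 at 3.02, Pla2g7 at 2.74, the receptor kinase gene Axl at 2.58, Ggct at 2.58, the matrix glycoprotein gene Sparc at 2.29, Prkg2 at 2.27, Aebp1 at 2.18, Igfbp3 at 2.15, Angptl2 at 2.10, Tnfaip6 at 2.08, Oaf at 1.93, Twist1 and Vim. Cluster 7 held 44.4% of the CD9hi UMIs of Klra4, 43.0% of S100a4, 47.1% of Sparc and 45.1% of Oaf, and without it these genes were at 4.14, 2.42, 1.58 and 1.28. The 15 lowest were mostly acinar or secretory genes. They were the lipase-related Pnliprp2 at -8.91 (-9.58 to -8.36), the trypsinogen gene Prss2 at -8.54, Reg1 at -7.44, Cel at -6.87, Reg3b at -6.85, Try5 at -6.68, Reg3g at -6.57, Cpb1 at -6.20, Clps at -6.096, Wfdc18 at -5.84, Lcn2 at -5.74, Reg2 at -5.60, Pnliprp1 at -5.33, Dmbt1 at -5.29 and Ctrb1 at -5.17. Cluster 11, of whole-tumour cells alone, held 97.1% of the whole-tumour Prss2 UMIs and 83.3% of those of Ctrb1. Without it the ratios were -5.41 for Pnliprp2, -3.65 for Prss2, -2.33 for Cel and -2.80 for Ctrb1, against -6.51 for Reg3b, -6.05 for Wfdc18 and -5.93 for Lcn2. Ctrb1 was also at 392 CPM in whole-tumour and 1.88 CPM in CD9hi cells of cluster 4 and at 501 CPM and 1.32 CPM in cluster 8. In cluster 3 the order was the opposite, with Ctrb1 at 404 CPM in 576 whole-tumour cells and 3692 CPM in 71 CD9hi cells.

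**Figure D1:**
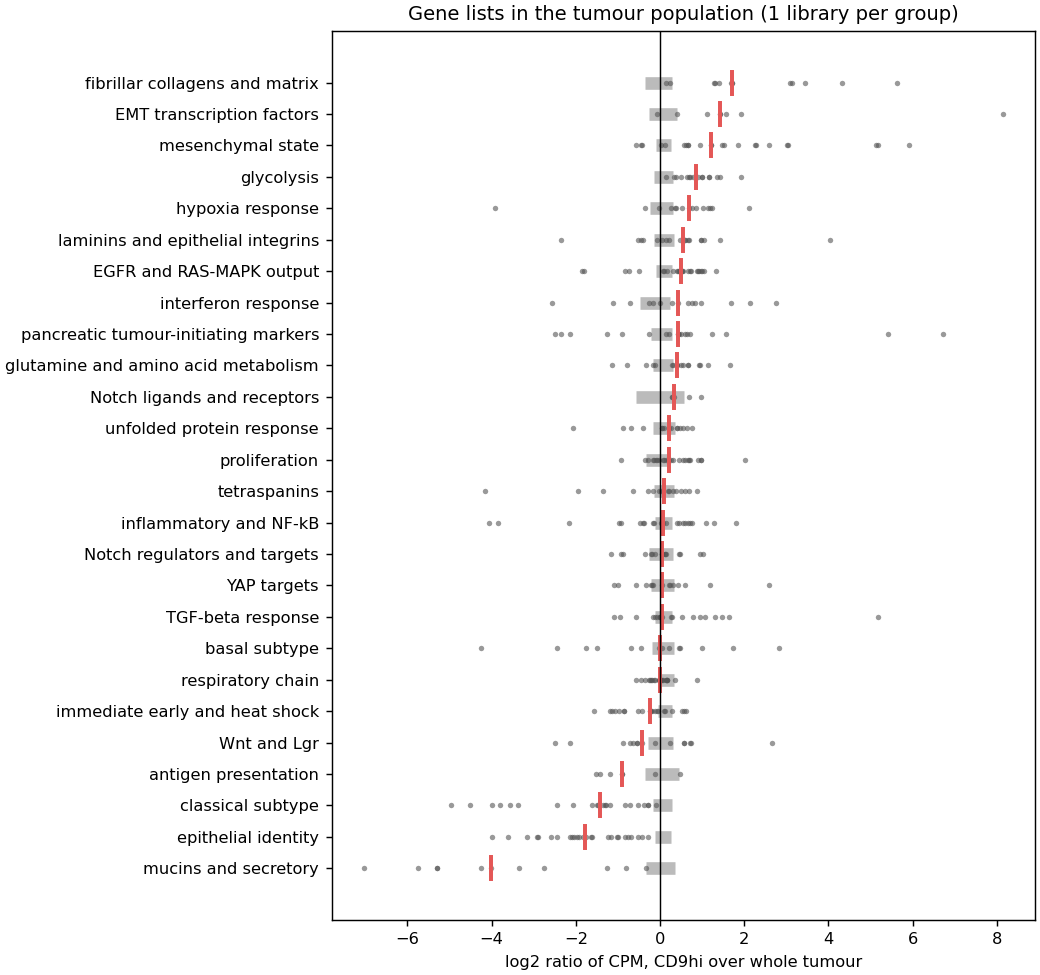
Log2 ratios of CPM, CD9hi over whole tumour, in the tumour population (x axis) for 26 gene lists (y axis), with a grey point per measured gene, a red line at the list median and a grey bar over the central 95% of medians of 10000 matched random lists. The epithelial median of -1.79 and the mesenchymal median of 1.202 lay outside the bars on opposite sides.

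Notch pathway genes were compared because the series concerns Jag1. Jag1 was higher in the CD9hi library, at 142 CPM against 87.2 CPM, a log2 ratio of 0.70 (0.65 to 0.75), while the receptors Notch1 and Notch2 were at 0.32 (0.19 to 0.46) and 0.27 (0.18 to 0.37) and the Notch target Hes1 at 0.04 (0.01 to 0.08). Of 5 measured ligands and receptors, 2 were higher, Dll4 at 0.97 and Jag1, and 0 lower, with a median of 0.32 at percentile 85.1. Without cluster 11 Jag1 was at 0.54, short of 1.5-fold, which left 1 higher. Of 16 regulators and targets, 2 were higher, the progenitor factor Sox9 at 1.01 and Rbpj at 0.95, and 3 lower (1 over the 3 shared clusters), Hes6 at -1.16, Lfng at -0.93 and Dtx3 at -0.88, with a median of 0.05 at percentile 48.4. Below the expression minimum, Jag2 was at -1.51 (-1.86 to -1.16), Notch3 at -0.45 (-0.86 to -0.0032) and Hey1 at 1.42 (0.92 to 2.00). Over the 3 shared clusters together Jag1 was at -0.10, Jag2 at 1.07 and Cdh1 at 0.18. Within them Jag1 was at 0.27 (0.11 to 0.43) in cluster 0, 0.32 (0.13 to 0.51) in cluster 6 and -0.43 (-0.56 to -0.30) in cluster 8, Cdh1 was at 0.57, 0.49 and -0.47, and each Jag2 interval included 0.

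Markers of pancreatic tumour-initiating cells moved in both directions. Of 19 measured, 7 were higher and 5 lower, with a median of 0.43 at percentile 99.9. Thy1 was at 6.72 (5.53 to 8.77, 4 UMIs in the whole tumour) and Cd34 at 5.41, whereas the Wnt-related receptor Lgr5 was at -2.51 and Prom1, which encodes CD133, at -2.35. The hyaluronan receptor gene Cd44 was at 0.64 (0.62 to 0.66). Thy1 is also in the fibroblast marker list, and without cluster 7 the count of higher genes was 4, and over the 3 shared clusters 1 was higher and 0 lower. Of 16 tetraspanins, 2 were higher, Cd63 at 0.89 and Cd9, and 4 lower, among them Tspan1 at -4.16 and Tspan13 at -1.95, with a median of 0.10 at percentile 58.2, against 0 higher in the clusters named ductal epithelial. Trp53, which the mouse line is built to delete, was detected at 192 CPM in the whole tumour and 230.4 CPM in the CD9hi library, a log2 ratio of 0.27 (0.23 to 0.30), and whether these 3′ counts lie outside the deleted part was not known here.

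Tumour subtype and secretory genes were mostly lower in the CD9hi library. Of 22 classical subtype genes, 17 were lower and 0 higher, with a median of -1.42 at percentile 0, among them the trefoil factors Tff1 at -4.98 and Tff2 at -3.80, Lgals4 at -4.51 and Vsig2 at -3.99. Of 11 mucin and secretory genes, 10 were lower, with a median of -4.02 at percentile 0, among them the immunoglobulin receptor Pigr at -7.04, Lcn2, and Muc4 at -5.30. Basal subtype genes split, with 3 of 14 higher and 5 lower and a median of 0.0060 at percentile 32.4, from Ly6d at -4.25 and Krt17 at -2.45 to Sprr1a at 1.73 and Cst6 at 2.83, and 5 were higher without cluster 5. Over the 3 shared clusters, 3 classical genes were lower and 5 higher, and 2 mucin genes were lower.

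Metabolic lists were higher for glycolysis and hypoxia. Of 16 glycolysis genes, 12 were higher and 0 lower, with a median of 0.85 at percentile 100, led by the lactate transporter Slc16a3 at 1.93, Pfkp at 1.41, Pgam1 at 1.36 and Pgk1 at 1.16. Of 15 hypoxia response genes, 8 were higher and 1 lower, with a median of 0.69 at percentile 99.98, with P4ha1 at 2.12 and Ndrg1 at 1.22 and, in the other direction, the carbonic anhydrase Car9 at -3.92. Glutamine and amino acid metabolism had 6 of 17 genes higher and 2 lower, with a median of 0.41 at percentile 99.7, including the serine synthesis gene Psat1 at 1.66 and Gls2 at -1.15. The respiratory chain had 1 of 25 genes higher, Ndufb9 at 0.87 and 0.33 without cluster 12, which held 35.3% of its CD9hi UMIs, and a median of -0.0071 at percentile 4.91. Over the 3 shared clusters 6 glycolysis genes, 6 hypoxia genes and 1 gene of amino acid metabolism were higher, and the glutamine and amino acid metabolism median was -0.10.

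Signalling and adhesion lists went in both directions. Of 18 laminin and integrin genes, 9 were higher and 1 lower, with a median of 0.53 at percentile 99.97, from Nid1 at 4.04 to the integrin Itgb6 at -2.35, against 3 lower without cluster 11 and 2 higher and 2 lower over the 3 shared clusters. EGFR and MAPK output genes had 10 of 26 higher and 4 lower, with a median of 0.50 at percentile 100, with Myc at 1.32, Ereg at 1.05, Spry1 at -1.86 and Erbb3 at -1.81, and 16 were higher without cluster 5 and 5 over the 3 shared clusters. Myc was at 474 CPM in cluster 12, of CD9hi cells alone, against 63.1 CPM in the median of the other large clusters. Its ratio without cluster 12 was not computed. Proliferation genes had 8 of 25 higher and 1 lower, Mki67 at -0.93, with a median of 0.21 at percentile 98.0, led by Rrm2 at 2.01, and the count of higher genes was 1 without cluster 5 and 1 without cluster 7, where 6 were lower, and over the 3 shared clusters 0 were higher or lower. The proliferation median turned to -0.58 in the clusters named ductal epithelial. TGF-beta response genes had 7 of 21 higher and 2 lower, with a median of 0.04 at percentile 36.8, from Tgfbi to the lower Ccn1 at -1.10 and Tgfbr1 at -0.96, and 2 were higher over the 3 shared clusters. YAP targets had 3 of 15 higher and 2 lower, with a median of 0.04 at percentile 41.1, from Axl and Ankrd1 at 1.19 to F3 at -1.01. Wnt and Lgr genes had 3 of 15 higher and 5 lower, with a median of -0.44 at percentile 0.45, from Wnt10a at 2.66 to Lgr4 at -2.15, and 1 was higher without cluster 11, 5 without cluster 5, and 0 lower over the 3 shared clusters, and the Wnt and Lgr median turned to 0.22 at a mean CPM of at least 50.

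Stress and immune lists also split. Immediate early and heat shock genes had 1 of 22 higher and 7 lower, with a median of -0.23 at percentile 0, led by Btg2 at -1.56, Ier2 at -1.20 and the chaperone Hspa1a at -1.14, and 4 were lower over the 3 shared clusters. Unfolded protein response genes had 2 of 15 higher and 3 lower, with a median of 0.21 at percentile 79.1, with the secretory cell factor Xbp1 at -2.07 and Chac1 at 0.76. Interferon response genes had 7 of 15 higher and 3 lower, with a median of 0.43 at percentile 99.9, with Ifit3 at 2.75, Ifit1 at 2.14, Isg15 at 1.69 and Ifi27 at -2.57, and 4 were higher without cluster 7, where the interferon response median was -0.074, and 3 over the 3 shared clusters. Isg15, Ifit3 and Ifit1 also led cluster 13, where Isg15 had 1525 UMIs in 90 cells, against 1070 UMIs in the 476 cells of cluster 7. Ratios without cluster 13 were not computed. Antigen presentation genes had 5 of 7 lower and 0 higher, with a median of -0.91 at percentile 0.02, led by Cd74 at -1.52 and Psmb8 at -1.42, and the median was 0.12 over all kept cells, macrophages included, while 0 were lower over the 3 shared clusters. Genes of the NF-kB list had 7 of 23 higher and 5 lower, with a median of 0.07 at percentile 47.8, from the complement gene C3 at -4.07 and Cxcl5 at -3.85 to Tnfaip2 at 1.81, and over the 3 shared clusters 9 were higher and 0 lower.

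Hybrid cells were those above the whole-tumour median for both epithelial and mesenchymal UMIs. They made up 23.3% (21.5 to 25.2) of 2104 thinned whole-tumour cells and 12.7% (11.8 to 13.7) of 4815 CD9hi cells. In the whole tumour 48.1% of cells were high for epithelial and 48.7% for mesenchymal genes, and in the CD9hi library 17.8% and 90.9%. The observed hybrid share was 0.997 times (0.920 to 1.08) the product of the single shares in the whole tumour and 0.786 times (0.729 to 0.846) in the CD9hi library. The classes are ranges and not cell types, and 15.7% and 7.77% of cells lay within 1 UMI of a boundary. At the upper quartile of the whole tumour the hybrid shares were 6.51% and 2.39%, and with boundaries at the median of both libraries pooled they were 14.8% and 13.9%.

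**Figure D2:**
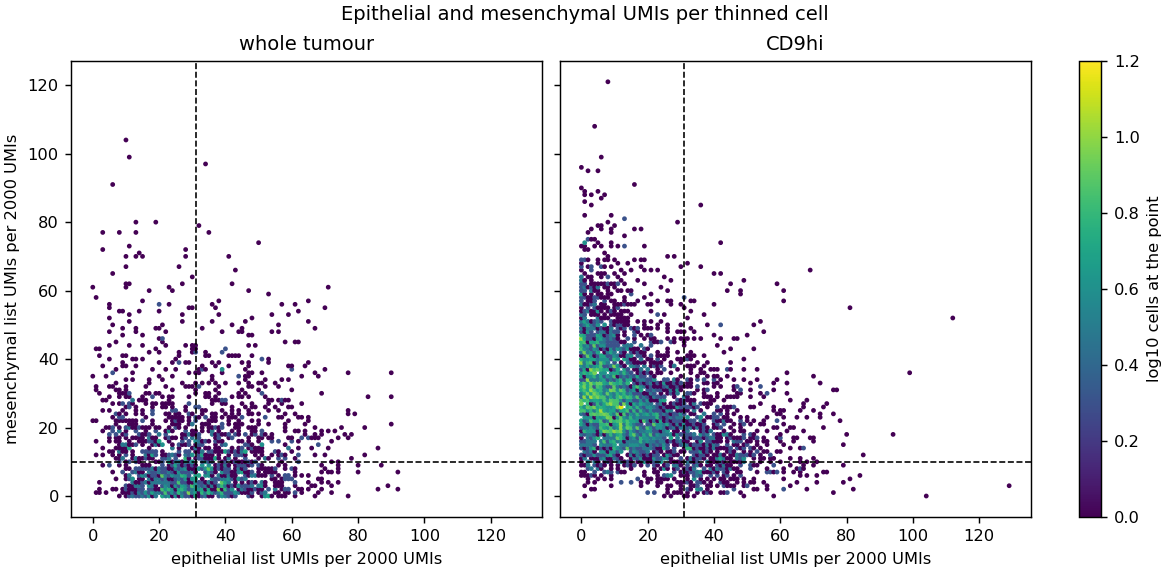
Mesenchymal list UMIs (y axis) against epithelial list UMIs (x axis) per cell thinned to 2000 UMIs, for the whole-tumour (left) and CD9hi (right) tumour populations, with colour for the log10 number of cells at a point and dashed lines at the whole-tumour medians of 31 and 10 UMIs. Hybrid cells lie above and to the right of the lines, 23.3% of whole-tumour and 12.7% of CD9hi cells.

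Jag1 was higher in hybrid cells than in either single class in both libraries. In the whole tumour Jag1 was at 156 CPM (148 to 165) in hybrid, 38.4 CPM (34.6 to 42.4) in epithelial-only and 135 CPM (128 to 143) in mesenchymal-only cells, and in the CD9hi library at 198 CPM (190.3 to 206), 112 CPM (103 to 121) and 137 CPM (134.9 to 139.8) in these classes. The log2 ratio of hybrid over mesenchymal-only cells was 0.21 (0.10 to 0.32) and 0.53 (0.46 to 0.59), and over epithelial-only cells 2.03 (1.86 to 2.19) and 0.83 (0.69 to 0.96). Ranked by the lower of both ratios, Jag1 was number 386 of 2721 genes in the whole tumour and 22 of 2837 in the CD9hi library. In the whole tumour the ratio to mesenchymal-only cells was 0.041 with the mean of per-cell CPM and 0.028 with no cell filter. Within single clusters with at least 20 cells of both classes, the median ratio was -0.12, with 3 of 7 values above 0.

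Other Notch genes and Cd9 differed in their pattern. Hes1 in hybrid cells was above epithelial-only cells by 0.27 and 0.13 and above mesenchymal-only cells by 0.36 and 0.48 in the whole tumour and the CD9hi library, but the CD9hi Hes1 log2 hybrid over epithelial only was -0.33 with boundaries at the pooled median. Notch2 was at 0.42 and 0.45 over epithelial-only cells, and its ratios to mesenchymal-only cells, -0.20 (-0.43 to 0.016) and 0.052 (-0.088 to 0.19), were not distinguishable from 0 at this depth, nor were the Notch1 ratios to either class. Jag2, at low counts, was at 1.05 (0.21 to 1.94) and 1.70 (1.10 to 2.27) over mesenchymal-only cells. Over epithelial-only cells its ratios, -0.15 (-0.84 to 0.52) and 0.21 (-0.73 to 1.24), were not distinguishable from 0. Notch3 and Hey1, also at low counts, were lower than in mesenchymal-only cells of the CD9hi library, at -2.34 (-4.24 to -0.96) and -1.86 (-2.94 to -0.95). In the whole tumour these 2 intervals included 0, at 1.02 (-0.71 to 2.95) and -1.21 (-3.05 to 0.37). Cd9 in the whole tumour was at 1640.2 CPM in hybrid, 899 CPM in epithelial-only and 2576 CPM in mesenchymal-only cells, and in the CD9hi library at 2536 CPM, 2231 CPM and 2367 CPM.

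**Figure D3:**
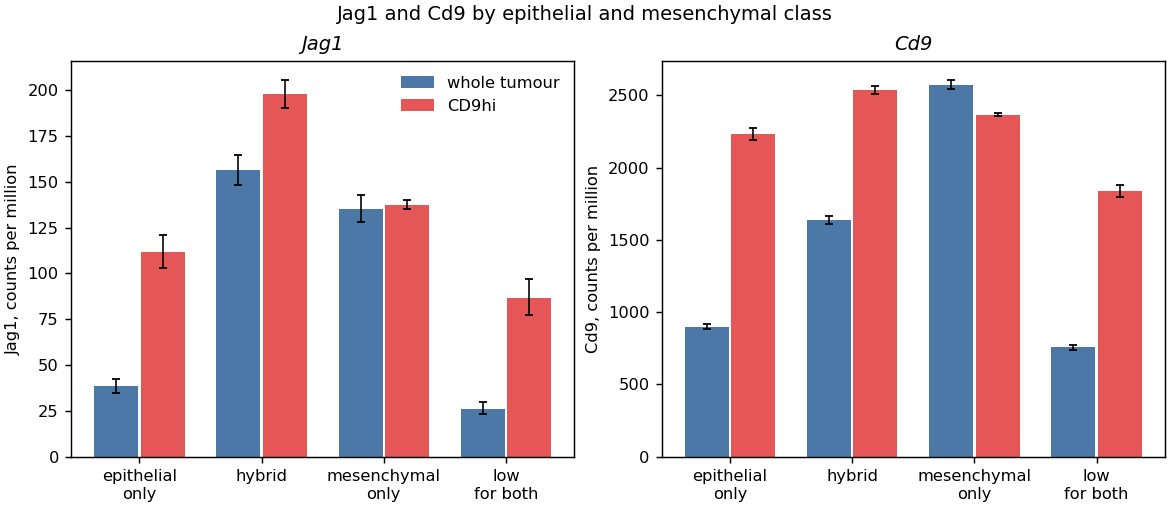
Jag1 (left) and Cd9 (right) in CPM (y axes) by epithelial and mesenchymal class (x axes), with a bar per library and exact Poisson 95% intervals, which cover counting error only. Jag1 was highest in hybrid cells, at 156 CPM in the whole tumour and 198 CPM in the CD9hi library.

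The genes with the largest excess in hybrid cells over both single classes were mostly different in the 2 libraries. In the whole tumour they included the basal keratin Krt17 at 1.59, the laminin gene Lama3 at 1.37, Trbc1 at 1.13, Dyrk3 at 0.97, Krt7 at 0.92, Sox11 at 0.89, Gzme at 0.88, Cdkn1c at 0.86 and Ly6e at 0.86, as the lower of both log2 ratios. In the CD9hi library they included Mab21l4 at 1.21, Ccn2 at 1.15, Fbxo32 at 0.96, the cytokine gene Csf2 at 0.94, Nt5e at 0.74, Pkp1 at 0.70, Bhlhe40 at 0.66, Endod1 at 0.66 and Jam2 at 0.63. Krt7 and Ccn2 are in the lists that set the classes. Trbc1, Dyrk3 and Fbxo32 were at least 1.5-fold higher in both libraries.

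Detection of Jag1 was compared between cells with and without a Cd9 UMI. In the whole tumour 15.9% of Cd9-positive and 8.18% of Cd9-negative thinned cells had a Jag1 UMI, a difference of 7.67 percentage points (4.56 to 10.8). In the CD9hi library the shares were 20.8% and 20.3%, a difference of 0.486 (-5.26 to 6.23), which was not distinguishable from 0 at this depth. The background in acinar-like cells was 1.57% (0.511 to 3.62). Whole-tumour clusters 4 and 11, of 552 and 264 cells, were low in both genes. Cd9 was at 687 CPM and 332 CPM and Jag1 at 18.98 CPM and 21.9 CPM in them. The whole-tumour difference was not computed within clusters, so it cannot be told apart from a difference between clusters. Over all cells of the tumour population Jag1 was detected in 14.1% and 20.7% after thinning and in 49.2% and 68.7% without it, against 16.9% of acinar-like cells.

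Transcriptome entropy, which StemID uses as a measure of stem-like expression, had a median of 9.16 bits in the whole-tumour and 9.36 bits in the CD9hi tumour population. The median of hybrid cells was above that of epithelial-only cells by 0.20 bits in the whole tumour and by 0.039 bits in the CD9hi library. This was not computed within clusters, so it cannot be told apart from a difference between clusters. Whole-tumour clusters 4 and 11 had medians of 8.97 and 8.95 bits and hybrid shares of 2.19% and 4.58%. Whole-tumour cells of cluster 3 had 9.29 bits and a hybrid share of 59.3%. Class medians were 9.30 and 9.40 bits in hybrid, 9.10 and 9.36 in epithelial-only, 9.22 and 9.36 in mesenchymal-only cells, and 8.92 and 9.32 in cells low for both. Proliferating cells made up 4.71% (3.84 to 5.70) and 6.50% (5.82 to 7.23) of the whole-tumour and CD9hi tumour populations. Clusters 5 and 7, made up almost wholly of CD9hi cells, had proliferating shares of 16.6% and 22.1% in that library. In its largest clusters 0, 1 and 2 the shares were 2.62%, 1.94% and 0.994%. The exact CD9hi share without clusters 5 and 7 was not computed. The cluster values place it below the 4.71% of the whole tumour, so the higher CD9hi share rested on these clusters. In hybrid cells the proliferating shares were 3.26% (1.87 to 5.24) and 3.105% (1.88 to 4.81). The proliferating shares were 14.3% and 15.9% when cells were thinned to 4000 UMIs, with the same 3 UMIs required.

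Clusters were described by number because a cluster mostly of 1 library may be that library. Jag1 was highest in cluster 8, at 319 CPM in whole-tumour and 237 CPM in CD9hi cells, in cluster 1, at 274 CPM and 265 CPM, and in cluster 2, at 248 CPM in CD9hi cells, among clusters with at least 20 cells of the library. It was low in the trefoil factor cluster 4, at 18.98 CPM in whole-tumour cells, and in cluster 5, at 11.9 CPM in CD9hi cells. Cd9 ranged from 147 CPM in acinar-like cluster 9 to 3298 CPM in cluster 0 of the whole tumour. The hybrid share was 60.3% in cluster 3, where 89.0% of cells came from the whole tumour, and 40.0% in cluster 1, where 94.3% came from the CD9hi library. Cluster 17, of 16 whole-tumour cells, had the tuft cell genes Trpm5 at 494 CPM and Dclk1 at 2010 CPM.

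**Figure D4:**
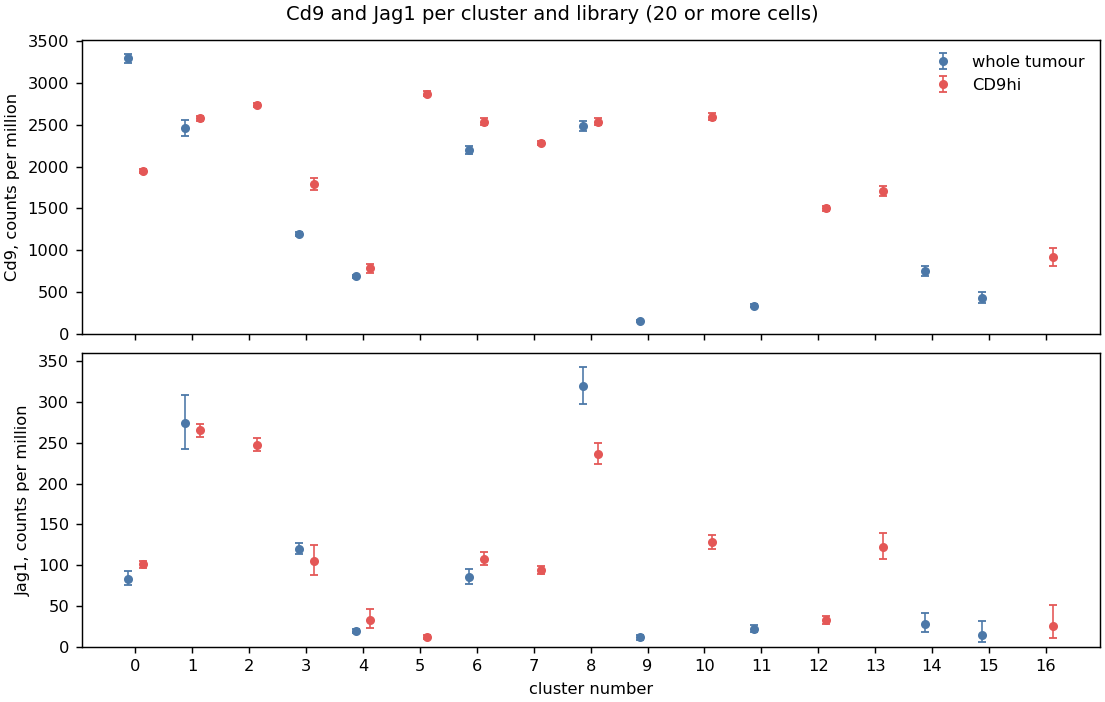
Cd9 (top) and Jag1 (bottom) in CPM (y axes) per cluster (x axis) and library, for clusters with at least 20 cells of the library, with exact Poisson 95% intervals that cover counting error only. Jag1 was highest in cluster 8 of the whole tumour at 319 CPM, and Cd9 in cluster 0 of the whole tumour at 3298 CPM.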

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

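The chromosome test and the test of the genes next to Myc were chosen after the result was seen, while the tests within clusters were fixed before their values were computed.

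Cd9 in hybrid over mesenchymal-only cells pointed in opposite directions in the 2 libraries, at -0.65 in the whole tumour and 0.10 in the CD9hi library on the log2 scale, and this difference was not tested. TdTomato, a reporter outside the main measurement, had 6 UMIs in the whole-tumour and 10 UMIs in the CD9hi library, above the 3 counts that a count of 0 allows. It was at 9.29 CPM (3.02 to 21.7) in 36 macrophage-like and fibroblast-like cells and at 0.060 CPM (0.027 to 0.11) in the tumour population, with 0.12 CPM (0.032 to 0.31) from 4 UMIs in its clusters 5, 7 and 12. GFP had 0 UMIs in both libraries, and it was not known here whether its added sequence reaches the transcript 3′ end that these libraries read, so this says nothing about the sort.

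Jag1 was higher in hybrid cells than in both single classes of each library. The excess may come from the clusters in which hybrid cells lie, because within clusters the median log2 ratio over mesenchymal-only cells was -0.12. Its 7 values ran from -1.17 to 0.52, with the interval above 0 in 2 and below 0 in 3. Doublets stayed open, because the ratio first used against them was the pattern itself, and a biological explanation within clusters was not tested.

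The libraries differed in Cd9, epithelial and mesenchymal genes. Different shares of cell states could account for part of this. The mesenchymal median averaged 0.50 over the 3 shared clusters, below the bound of 0.60 that would have argued against this explanation. It was above the 0.2 that the explanation needed, so for mesenchymal genes this cannot be told apart. The mesenchymal median was 0.38, 0.94 and 0.17 in clusters 0, 6 and 8. The epithelial median was -1.79 over the population and 0.30, -0.31 and -0.65 in these clusters, with a mean of -0.22. The Cd9 log2 ratio was 0.69 over the population and averaged -0.18 in them. No bound was set for epithelial genes or Cd9. Different tumours or clones may also contribute, because genes of chromosome 6 were shifted by -0.39 from the median of chromosomes in cluster 0 and by -0.36 in cluster 6, beyond the highest of 1000 shuffles at 0.140 and 0.110 in these clusters, but by -0.037 in cluster 8, and Cd9 lies on this chromosome in GRCm38.p6, where 99.3% of the genes were matched. The CD9 sort itself stays open and untested, with 1 library per group.

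Genes next to Myc were high in cluster 12, which held 212 CD9hi cells. A copy gain may account for this, but the test was changed until its bound was met. The unbroken run of raised genes at Myc held 2 genes, against 6 for the longest run in shuffled gene orders, and the longest run of 13 genes ended 14 genes from Myc, so both earlier forms failed. In the third form, 13 of the 25 genes centred on Myc were at least 2-fold higher, against at most 11 in 1000 shuffles. Other explanations were not tested, and DNA was not measured.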

How the results depend on the processing

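The alternatives without clusters 5, 7, 11 or 12 and over the clusters with at least 100 cells of each library were chosen after the result was seen, as was the Cd9 level over clusters named ductal epithelial. No paired analysis was possible because each group had 1 library. Of 2521 values over 30 alternatives, 1796 stayed within their interval or, for counts, within 1.5 times, 720 moved further and 5 changed direction. A direction was counted for log2 ratios only from 1.5-fold, and for all values only where the counting interval excluded no difference. The second condition was set after a first table had been seen, and it left out 13 changes of sign, 5 of the hybrid share and 8 of Jag1 and Notch genes by class. Below 1.5-fold, 20 more values with an interval away from no difference changed sign. Across the 10 alternatives planned for it, the Cd9 log2 ratio stayed between 0.68 and 0.88, and over all 16 it ran from -0.33 to 0.88. TMM and median-of-ratios scaling shifted all log2 ratios, with -0.117 and -0.152 subtracted from each. The 5 changes of direction were those of Cd9, Jag1, Jag2 and Cdh1 over the shared clusters and of the antigen presentation median over all kept cells, and the cause was not tested. For the other shifts the cause was not tested. Of 1840 list values, 1263 stayed and 573 moved, against 402 and 75 of 477 for Jag1 and Notch genes by class.

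Among the 20 values below 1.5-fold, the proliferation median was -0.58 over clusters named ductal epithelial, -0.19 with doublets removed at 2 times the expected rate, -0.13 with no cell filter, -0.14 at a mean CPM of at least 50, -0.20 without cluster 7 and -0.065 over the shared clusters. The Wnt and Lgr median was 0.22 at a mean CPM of at least 50 and 0.22 over the shared clusters, where glutamine and amino acid metabolism median was -0.10, tetraspanins median was -0.0081, Notch2 log2 ratio as a list member was -0.011 and Notch3 log2 ratio as a list member was 1.21. The interferon response median was -0.074 without cluster 7, the YAP targets median was -0.15 and the inflammatory and NF-kB median was -0.012 without cluster 11, and the TGF-beta response median was -0.0016 at a mean CPM of at least 50. The CD9hi Hes1 log2 hybrid over epithelial only was -0.33 with boundaries at the pooled median and -0.31 at the whole-tumour upper quartile, where CD9hi Cd9 log2 hybrid over epithelial only was -0.030.

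With no cell filter, the Cd9 level log2 ratio was 0.76, epithelial identity median was -1.56, mesenchymal state median was 1.08 and pancreatic tumour-initiating markers median was 0.29. The number of pancreatic tumour-initiating markers genes higher was 4, whole-tumour tumour population share was 87.4%, CD9hi tumour population share was 89.9% and whole-tumour hybrid share was 26.6%. The whole-tumour Jag1 log2 hybrid over epithelial only was 2.19, whole-tumour Jag1 log2 hybrid over mesenchymal only was 0.028, whole-tumour share with a Cd9 UMI was 68.5% and CD9hi hybrid share was 18.8%. The CD9hi observed over product of single shares was 0.879, CD9hi Jag1 log2 hybrid over mesenchymal only was 0.40 and CD9hi share with a Cd9 UMI was 94.0%. Over all kept cells, the Cd9 level log2 ratio was 0.88, epithelial identity median was -1.69, mesenchymal state median was 1.40 and Notch ligands and receptors median was 0.51. The antigen presentation median was 0.12 and whole-tumour share with a Cd9 UMI was 69.0%.

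With the mean of per-cell CPM, the Cd9 level log2 ratio was 0.78, epithelial identity median was -1.68, Notch ligands and receptors median was 0.48 and whole-tumour Jag1 log2 hybrid over mesenchymal only was 0.041. The CD9hi Jag1 log2 hybrid over epithelial only was 0.61. Over clusters named ductal epithelial, the Cd9 level log2 ratio was 0.51, epithelial identity median was -1.13, mesenchymal state median was 0.36 and number of mesenchymal state genes higher was 7. The number of mesenchymal state genes lower was 2, Notch ligands and receptors median was 0.59, pancreatic tumour-initiating markers median was 0.36 and whole-tumour share with a Cd9 UMI was 80.9%. The CD9hi hybrid share was 16.3%.

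With no doublets removed, the epithelial identity median was -1.63, mesenchymal state median was 1.13, pancreatic tumour-initiating markers median was 0.27 and CD9hi tumour population share was 90.4%. The CD9hi hybrid share was 13.9% and CD9hi Jag1 log2 hybrid over mesenchymal only was 0.43. With doublets removed at 2 times the expected rate, the epithelial identity median was -1.64, mesenchymal state median was 1.11, pancreatic tumour-initiating markers median was 0.26 and CD9hi tumour population share was 89.6%. The CD9hi hybrid share was 13.8%.

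At a mean CPM of at least 50, the epithelial identity median was -1.17, number of epithelial identity genes lower was 13, mesenchymal state median was 0.67 and number of mesenchymal state genes higher was 8. The Notch ligands and receptors median was 0.70, number of Notch ligands and receptors genes higher was 1, pancreatic tumour-initiating markers median was 0.49 and number of pancreatic tumour-initiating markers genes higher was 4. The number of pancreatic tumour-initiating markers genes lower was 2. With boundaries at the pooled median, the whole-tumour hybrid share was 14.8%, whole-tumour observed over product of single shares was 0.893, CD9hi hybrid share was 13.9% and CD9hi observed over product of single shares was 0.646. The CD9hi Jag1 log2 hybrid over epithelial only was 0.58 and CD9hi Jag1 log2 hybrid over mesenchymal only was 0.72.

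With boundaries at the whole-tumour upper quartile, the whole-tumour hybrid share was 6.51%, whole-tumour observed over product of single shares was 1.13, whole-tumour Jag1 log2 hybrid over epithelial only was 1.69 and whole-tumour Jag1 log2 hybrid over mesenchymal only was 0.33. The CD9hi hybrid share was 2.39%, CD9hi observed over product of single shares was 0.483, CD9hi Jag1 log2 hybrid over epithelial only was 0.55 and CD9hi Jag1 log2 hybrid over mesenchymal only was 0.73. Thinned to 4000 UMIs, the whole-tumour Jag1 log2 hybrid over epithelial only was 2.23, whole-tumour Jag1 detection difference was 15.6, whole-tumour median entropy was 9.58 and whole-tumour proliferating share was 14.3%. The whole-tumour share with a Cd9 UMI was 90.3%, CD9hi Jag1 log2 hybrid over epithelial only was 1.01, CD9hi median entropy was 9.79 and CD9hi proliferating share was 15.9%. The CD9hi share with a Cd9 UMI was 99.1%.

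Thinned to 1000 UMIs, the whole-tumour Jag1 detection difference was 3.80, whole-tumour median entropy was 8.66, whole-tumour entropy of hybrid minus epithelial only was 0.14 and whole-tumour proliferating share was 2.40%. The whole-tumour share with a Cd9 UMI was 60.1%, CD9hi median entropy was 8.84, CD9hi proliferating share was 2.63% and CD9hi share with a Cd9 UMI was 85.5%.

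With Scrublet's automatic threshold, the Cd9 level log2 ratio was 0.70. With the TMM factor, the Cd9 level log2 ratio was 0.81, epithelial identity median was -1.67, mesenchymal state median was 1.32 and pancreatic tumour-initiating markers median was 0.55. With the median-of-ratios factor, the epithelial identity median was -1.64, mesenchymal state median was 1.35, Notch ligands and receptors median was 0.48 and pancreatic tumour-initiating markers median was 0.59. Without the 2% of cells highest in UMIs, the mesenchymal state median was 1.18. Under a 2-fold rule, the number of Notch ligands and receptors genes higher was 0 and number of pancreatic tumour-initiating markers genes higher was 4. With no expression minimum, the number of Notch ligands and receptors genes lower was 2, pancreatic tumour-initiating markers median was 0.36 and number of pancreatic tumour-initiating markers genes lower was 8. Under the strict filter, the whole-tumour tumour population share was 88.7% and whole-tumour acinar-like share was 10.1%. At Leiden resolution 1.6, the CD9hi tumour population share was 96.0%. With each library clustered alone, the CD9hi tumour population share was 96.0% and CD9hi acinar-like share was 0%. Without mitochondrial and ribosomal protein genes, the whole-tumour median entropy was 9.10 and CD9hi median entropy was 9.30. Requiring 2 proliferation UMIs, the whole-tumour proliferating share was 12.9% and CD9hi proliferating share was 15.7%. Requiring 5 proliferation UMIs, the whole-tumour proliferating share was 1.47% and CD9hi proliferating share was 2.53%.

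Without cluster 5, the Cd9 level log2 ratio was 0.65, epithelial identity median was -1.63, mesenchymal state median was 1.35 and Notch ligands and receptors median was 0.47. The pancreatic tumour-initiating markers median was 0.53, CD9hi hybrid share was 14.4% and CD9hi Jag1 log2 hybrid over mesenchymal only was 0.35. Without cluster 11, the Cd9 level log2 ratio was 0.53, epithelial identity median was -1.73, number of mesenchymal state genes lower was 2 and Notch ligands and receptors median was 0.52. The number of Notch ligands and receptors genes higher was 1, pancreatic tumour-initiating markers median was 0.38, whole-tumour share with a Cd9 UMI was 80.7% and CD9hi hybrid share was 10.3%. The CD9hi observed over product of single shares was 0.714.

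Over the 3 shared clusters, the Cd9 level log2 ratio was -0.33, Jag1 log2 ratio as a list member was -0.10, Jag2 log2 ratio as a list member was 1.07 and Cdh1 log2 ratio as a list member was 0.18. The epithelial identity median was -0.50, number of epithelial identity genes lower was 9, mesenchymal state median was 0.19 and number of mesenchymal state genes higher was 7. The number of mesenchymal state genes lower was 1, Notch ligands and receptors median was -0.011, number of Notch ligands and receptors genes lower was 1 and pancreatic tumour-initiating markers median was 0.16. The number of pancreatic tumour-initiating markers genes higher was 1, number of pancreatic tumour-initiating markers genes lower was 0, whole-tumour share with a Cd9 UMI was 94.5% and CD9hi share with a Cd9 UMI was 94.8%. Without cluster 12, the Cd9 level log2 ratio was 0.72, epithelial identity median was -1.70 and CD9hi Jag1 log2 hybrid over mesenchymal only was 0.44.

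Without cluster 7, the epithelial identity median was -1.58, mesenchymal state median was 1.09, pancreatic tumour-initiating markers median was 0.27 and number of pancreatic tumour-initiating markers genes higher was 4. The CD9hi hybrid share was 14.1% and CD9hi Jag1 log2 hybrid over mesenchymal only was 0.44.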

Other observations

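All tests named here on clusters 5 and 12 were chosen after the result was seen, as were the genes named.

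Cluster 12, of CD9hi cells alone, had high levels of a stretch of neighbouring genes on chromosome 15, in the gene order of GRCm38.p6 with 98.1% of genes matched. From Ccn3 to Pvt1, 26 of 28 measured genes were at least 2-fold higher than the median of the other large clusters, with a median log2 ratio of 3.15, and the exceptions were Fbxo32 at 0.21 and Lratd2 at 0.69. The ends of this stretch were set by the raised genes themselves. It starts with the longest unbroken run of raised genes and ends with the run at Myc. Among all 9109 ordered genes 8.97% were raised, but the count in a stretch chosen this way cannot be compared fairly with that share. Before its start, Samd12, Tnfrsf11b and Mal2 were not raised, while Ext1 beyond them was at 3.63. The proto-oncogene Myc was at 474 CPM against 63.1 CPM, its neighbour Pvt1 at 235 CPM against 8.93 CPM, and the respiratory chain gene Ndufb9 at 3418 CPM against 308 CPM. The same cluster had the cell cycle inhibitor gene Cdkn2a at 2303 CPM and Jag1 at 32.7 CPM.

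Cluster 5, of 585 CD9hi and 3 whole-tumour cells, had little nuclear RNA. Malat1 was 152-fold lower than the median of the other large clusters, at 157 CPM against 23838 CPM, Neat1 was 164-fold lower and Xist was at 5.90 CPM against 527 CPM. The immediate early genes Jun, Fos and Klf6 were 151-fold, 115-fold and 116-fold lower. Cytoplasmic transcripts were not low, with Lgals1 at 10472 CPM against 2085 CPM and Gapdh at 5363 CPM against 2254 CPM. Median log2 ratios per chromosome ran from -1.07 on chromosome 12 to -0.35 on chromosome 10, and the X chromosome was at -0.039.

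Cluster 7, of 476 CD9hi cells, had the mesenchymal factor Prrx1 at 239 CPM, Dcn at 87.9 CPM and Cdkn2a at 1479 CPM. The 9 fibroblast-like cells had Prrx1 at 219.5 CPM, Dcn at 3314 CPM and Cdkn2a at 335 CPM. Proliferating cells made up 22.1% of cluster 7 and 16.6% of CD9hi cells in cluster 5.

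Cluster 13, of 88 CD9hi and 2 whole-tumour cells, was led by the interferon response genes Isg15, Ifit3, Ifit1 and Irf7.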
